A study of Rattus norvegicus with 172 samples.

How the data were processed

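RNA of dentate granule cells, the principal neurons of the dentate gyrus, was measured on 172 one-colour Affymetrix arrays from 164 male Sprague-Dawley rats. Per the labels, granule cells were cut by laser from 10 µm sections of the hippocampus, total RNA with an integrity number above 7 was pooled to at least 10 ng per rat, and the RNA was amplified and hybridised as biotin-labelled cRNA. The rats came from 7 laboratories, which ran 4 models of epilepsy, and each laboratory had its own controls and 3 times or stages, which made 28 groups. The laboratories of a model are called A and B here. The deposited values are linear signal intensity per probe set, and the submitters' processing notes name MAS5, with no version. Tested on the values, each array had been scaled to the same trimmed mean of 150.04 to 150.06 after leaving out the lowest and highest 2% of probe sets.

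The table held 31099 probe sets, of which 57 were array controls and were left out of the tests. Of the other 31042, 20826 carried 1 gene symbol, 436 carried several and 9780 carried none, and those with several or none were not tested. A probe set was kept when it lay above the median of its own array in at least 6 rats, which 19949 did. A gene with several such probe sets was represented by the one with the highest mean over all rats, which concerned 2677 of the 10761 genes tested. No genome positions were at hand, so genes are given by symbol alone. A value of 16 was added to each signal before the log2 transformation. The 8 rats with a repeated array (SSSE day 1 rat 6, kainate laboratory A day 3 rat 5, kindling laboratory A stage 4 rat 6 and pilocarpine laboratory A control rats 1 to 5) entered as the mean of both, whose values correlated at 0.946 to 0.995 across probe sets. In kainate laboratory A day 3 rat 5 and pilocarpine laboratory A control rat 5 the repeat was less alike than the closest other rat of the group. In 2 rats, SSSE day 1 rat 3 and kindling laboratory A stage 2 rat 4, one label contradicted the others, and each was kept in the group that most of its labels gave. Rat numbers were not used as pairs, because no label says that they pair rats. A term for the rat number was among the alternatives fixed beforehand. After group means were removed, 50 of the 164 rats correlated best with a rat of their own number in another group of the same laboratory, where chance gives 27.2.

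Changes were tested with limma 3.58.1 in R 4.3.3, while data.table (version 1.17.8) read the values and plots were drawn by matplotlib 3.10.9. Each model was fitted with 1 mean per group, and each time or stage was compared with the controls of the same laboratory, averaged over the laboratories with equal weight. Counts for a single laboratory come from the same fit, with its common spread, and counts for a laboratory fitted alone are given beside them. Genes with a Benjamini-Hochberg adjusted p under 0.05 counted as changed, at any fold. Moderated F-tests compared the laboratories of a model and the times of a model. A fit over all 28 groups compared the models of status epilepticus (SE), which are pilocarpine, kainate and SSSE. Genes shared by the SE models were those changed in the same direction in all 3 separate fits. Errors are the standard errors of the fit, except where resampling is named, and n counts rats. The number of arrays limits the precision.

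There were 23 gene lists of cell types and pathways. They were tested with camera at a preset correlation of 0.01, adjusted over all 276 tests of 23 lists in 12 comparisons, and again with an estimated correlation. The rotation test fry, which asks whether the genes of a list move one way on balance and does not compare them with other genes, was run beside it. The samples and their groups, the tests, the lists, the rule for naming genes and all but 2 of the alternatives were fixed before the data were examined. For each comparison with control the named genes are the 8 largest rises and 8 largest falls among changed genes with the same sign in every laboratory, passing over provisional symbols. To these were added up to 3 changed members of each list described, and Fos, Arc, Bdnf, Npy, Gfap, Prox1 and Calb1 whatever their values. For shared genes they are the 8 largest rises and falls by the mean of the 3 models, and for F-tests the 5 smallest p.

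Array checks comprised the median signal, the log2 ratio of the 3' to the 5' control probe sets of Gapdh and beta-actin, and the correlation of each array with the others of its group. The signal and the ratios were compared between each time and its controls within each laboratory by exact permutation tests, 63 in all. The plan named Spearman's correlation. A rat was doubted, by a rule chosen after the data were seen, when its median Pearson correlation lay more than 0.02 under that of its group. This held for 5 rats, and for 6 by Spearman's correlation, with 5 in both. A day 1 score was also devised after the data were seen. It gave the size of each rat's change from its laboratory's controls along the day 1 effects of another model, where 1 is the full size. That model was pilocarpine for kainate rats and kainate for all others. Each treated rat of the SE models was also assigned to the time of that other model with which its changes correlated best.

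Alternatives were a pseudocount of 1, quantile normalization, no filter and a stricter filter on dim probe sets, the mean of all probe sets of a gene, and the first array of repeated rats. Others were leaving out the 2 rats with contradicting labels, a term for the rat number, 1 fit over all 28 groups, each laboratory alone and leaving out each rat in turn. After the data were seen, 2 were added: the second array of repeated rats, and leaving out the 5 doubted rats. Up to 100 splits of the same rats, the real one among them, were tried for each count. Single rats apart from their group were sought with Dixon's test at 95%. When the methods were tested on simulated data with changes of 1.5, 2 and 4-fold put into 67, 67 and 66 genes, the tests against control recovered 62.7% to 98.5% of the 1.5-fold changes. Tests of a difference between laboratories recovered 10.4% of these in pilocarpine, 20.9% in kainate and 55.2% in kindling, and 43.3% to 47.8% were found as shared by the SE models. In 1 simulated comparison the list test called the raised list and 1 of 22 unchanged lists. Genes were simulated as independent of each other, so this does not check the list test where genes of a list move together.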

Results

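Gene expression in laser-captured granule cells was compared between 4 rat models of epilepsy and controls. In the pilocarpine model (48 rats, laboratories A and B), 300 to 350 mg/kg of this cholinergic agonist started status epilepticus (SE), which was stopped after 90 min. In the kainate model (48 rats), hourly doses of 5 mg/kg of this glutamate receptor agonist were given until SE began. Laboratory A let SE end by itself after 6 to 8 h, while laboratory B gave a first dose of 7.5 mg/kg and stopped SE after 90 min. SSSE, self-sustaining status epilepticus, came from 1 laboratory (20 rats), and kindling, in which repeated stimulation brings on seizures of rising stage, from laboratories A and B (48 rats). Rats of the SE models were taken at day 1, day 3 or day 10, and kindled rats at stage 2, 4 or 5. Each group held 6 rats, except for 5 control, 5 day 3 and 4 day 10 rats of SSSE. Median signal per array ran from 27.9 to 54.2, and the highest signal per array from 3426 to 27431. Of 63 tests of array quality between a time and its controls, 4 had an unadjusted p under 0.05. With 6 rats against 6 no single one of them was able to pass adjustment. At pilocarpine day 1 in laboratory A the mean of the median signals was 36.4 against 42.7 in controls (exact p = 0.00216). Rats did not overlap when both arrays of a repeated control were averaged. First arrays of controls 1 to 5 lay at 45.5 to 54.2, but second arrays at 35.2 to 43.3, which overlap the day 1 rats (33.5 to 39.2). The other tests with an unadjusted p under 0.05 included a lower Gapdh ratio at kainate day 1 in laboratory A (1.11 against 1.5, p = 0.0216). They also included a lower actin ratio at SSSE day 1 (3.08 against 3.51, p = 0.0195) and a lower median signal at kainate day 10 in laboratory B (34.5 against 36.7, p = 0.0238). The first principal component, with 28.8% of the variance, set both pilocarpine laboratories and kainate laboratory B apart from the other laboratories. A small overlap remained between kainate laboratory A (highest score 3.25) and pilocarpine laboratory B (lowest 1.34).

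**Figure D1:**
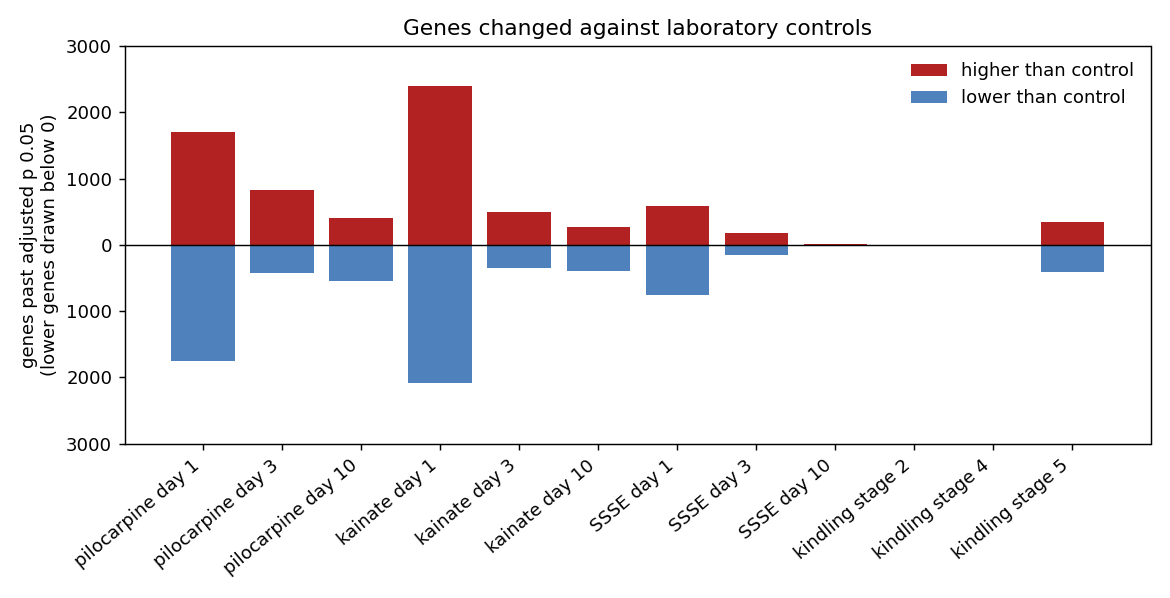
Number of genes past the adjusted threshold in each comparison with laboratory controls, with higher genes drawn above 0 and lower genes below. The bars reach 2393 higher and 2085 lower genes at kainate day 1, and there are none at kindling stages 2 and 4.

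Pilocarpine at day 1 asked how granule cells differ shortly after SE. Lox, which cross-links collagen and elastin, rose by 4.81 ± 0.45 on the log2 scale (standard error, n = 12 against 12 controls). Trh, the precursor of thyrotropin-releasing hormone, rose by 4.25 ± 0.46, and both lay beyond the range of the controls in 12 of 12 rats. Rgs4, a brake on G protein signalling, rose by 4.38 ± 0.60, Lgals3 (galectin-3) by 3.42 ± 0.31 and the protease inhibitor Timp1 by 3.10 ± 0.45. The falls were led by Plk5, a polo-like kinase enriched in granule cells, which fell by 3.38 ± 0.39, B3galt5 by 2.83 ± 0.27, Col25a1 by 2.71 ± 0.27, Calml4 by 2.64 ± 0.41, Rreb1 by 2.63 ± 0.28 and the neurotrophin Ntf3 by 2.53 ± 0.32. In all, 3454 of 10761 genes changed (1704 higher, 1750 lower), with 285 at least 2-fold higher and 207 at least 2-fold lower. Within this fit laboratory A passed 2429 genes and laboratory B 1626, and fitted alone 2355 and 1440. Across genes, which are not independent replicates, the effects of A and B correlated at 0.75.

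Of 26 measured immediate early genes, which respond fast to activity, 18 rose, 0 fell and 8 did not pass (21 higher and 0 lower adjusted over the list alone), led by Gadd45b at 2.70 ± 0.36 and Inhba at 2.40 ± 0.39. The list was higher than other genes (adjusted p = 2.0e-08 by camera, but adjusted p = 0.37 with an estimated correlation). Fry asks whether the genes of a list move one way on balance and does not compare them with other genes. Over all comparisons camera called 78 of 276 tests, fry 53, and camera with an estimated correlation 4, which were the microglia, proliferation and cholesterol lists at pilocarpine day 3 and the microglia list at kainate day 3. Of 19 inflammation genes, 16 rose, 1 fell and 2 did not pass (16 higher and 1 lower adjusted over the list alone; camera adjusted p = 1.0e-07, adjusted p = 0.254 with an estimated correlation), among them the chemokine Ccl2 at 2.86 ± 0.43 and Stat3 at 2.07 ± 0.21. Of 33 genes of matrix remodelling, 22 rose, 1 fell and 10 did not pass (24 higher and 1 lower adjusted over the list alone; camera adjusted p = 8.6e-08, adjusted p = 0.53 with an estimated correlation). Granule cell markers fell in 11 of 15, with 0 higher and 4 not passed (0 higher and 12 lower adjusted over the list alone; camera adjusted p = 4.9e-06, adjusted p = 0.254 with an estimated correlation). Astrocyte markers went both ways, with 2 of 15 higher, 8 lower and 5 not passed (2 higher and 8 lower adjusted over the list alone). The filament genes Vim and Gfap rose by 2.16 ± 0.30 and 1.10 ± 0.24, while the gap junction gene Gja1 fell by 1.57 ± 0.26 and the bicarbonate transporter Slc4a4 by 1.37 ± 0.21.

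At day 3 after pilocarpine, genes of glia and phagocytes were among the 8 largest rises, as were Lox at 2.70 ± 0.45 and Hspb1 at 2.41 ± 0.48. The filament gene Vim rose by 3.51 ± 0.30 (n = 12 against 12), Lgals3 by 3.09 ± 0.31, Gpnmb by 2.87 ± 0.36, the lysozyme gene Lyz2 by 2.65 ± 0.36 and Gfap by 2.43 ± 0.24. Vim, Lgals3, Gpnmb, Lyz2 and Gfap lay beyond the control range in 12 of 12 rats. Ryr1, a calcium release channel, fell by 2.15 ± 0.20, the activin antagonist Fst by 1.98 ± 0.26 and the growth factor Gdf10 by 1.95 ± 0.20. Altogether 1255 genes changed (833 higher, 422 lower; 508 in laboratory A, 390 in B, and 461 and 379 fitted alone), and the effects of A and B correlated at 0.63 across genes. With all 28 groups fitted together 2553 passed. Of 16 microglia and macrophage markers, 13 rose, 0 fell and 3 did not pass (15 higher and 0 lower adjusted over the list alone), including the complement gene C1qc at 1.91 ± 0.19 and Cd74 at 1.85 ± 0.27. Their list was higher by camera (adjusted p = 3.8e-18) and with an estimated correlation (adjusted p = 0.0311). Proliferation genes rose in 14 of 18, with 0 lower and 4 not passed (15 higher and 0 lower adjusted over the list alone; camera adjusted p = 6.7e-11, adjusted p = 0.0311 with an estimated correlation), such as Cdk1 at 1.62 ± 0.17 and Mki67 at 1.41 ± 0.17. Genes of cholesterol synthesis fell in 10 of 20, with 0 higher and 10 not passed (0 higher and 13 lower adjusted over the list alone; camera adjusted p = 9.1e-10, adjusted p = 0.0312 with an estimated correlation). Idi1, which makes an isoprenoid precursor, fell by 0.88 ± 0.18, and Insig1, a sterol sensor, by 0.74 ± 0.21.

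By day 10 after pilocarpine, Lox was higher by 3.02 ± 0.45 (n = 12 against 12), Rprm, a cell cycle inhibitor, by 2.05 ± 0.33, Lgals3 by 1.95 ± 0.31 and Car10 by 1.90 ± 0.27. Plk5 fell by 2.03 ± 0.39, Gdf10 by 1.89 ± 0.20 and the growth factor receptor Egfr by 1.47 ± 0.16. Microglia markers rose in 6 of 16, with 0 lower and 10 not passed (10 higher and 0 lower adjusted over the list alone; camera adjusted p = 8.5e-08, adjusted p = 0.254 with an estimated correlation). In total 961 genes changed (411 higher, 550 lower), and 2505 with all 28 groups fitted together. Laboratory B passed 902 genes and laboratory A 81, the effects correlated at 0.34 across genes, and fitted alone B passed 654 and A 67. Day 10 rats 1, 2 and 3 of laboratory B had day 1 scores of 1.04, 0.98 and 0.95, against 0.089 to 0.241 in laboratory A at day 10. The day 10 changes given above are means over both laboratories that include these 3 rats. Rat 2 of laboratory B was among the 5 doubted rats, with laboratory A day 10 rats 2 and 5. Without the doubted rats 580 genes passed, of which 476 were among the 961, in the same direction.

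Kainate at day 1 changed 4478 genes (2393 higher, 2085 lower), of which 277 were at least 2-fold higher and 231 at least 2-fold lower. Trh rose by 4.94 ± 0.35 (n = 12 against 12), Lox by 4.93 ± 0.27, the serine protease Prss23 by 4.68 ± 0.19 and the small heat shock protein Hspb1 by 4.32 ± 0.26. All 4 lay beyond the control range in 12 of 12 rats. Falls were largest for Plk5, by 3.81 ± 0.28, Ntf3, by 3.39 ± 0.38, the glypican Gpc3, by 3.07 ± 0.24, and the zinc finger factor Rreb1, by 2.98 ± 0.14. Laboratory A passed 2323 genes and laboratory B 3513, in the reverse order of the 3128 and 2686 when each was fitted alone, with a correlation of 0.85 across genes. Granule cell markers fell in 14 of 15, with 0 higher and 1 not passed (0 higher and 14 lower adjusted over the list alone; camera adjusted p = 1.0e-07, adjusted p = 0.0654 with an estimated correlation). Among them were C1ql3, by 1.53 ± 0.16, and the transcription factor Prox1, by 0.74 ± 0.09. Inflammation genes rose in 14 of 19, with 1 lower and 4 not passed (14 higher and 1 lower adjusted over the list alone; camera adjusted p = 7.0e-06, adjusted p = 0.254 with an estimated correlation), led by Serpina3n at 3.22 ± 0.29. Matrix remodelling genes rose in 23 of 33, with 1 lower and 9 not passed (23 higher and 1 lower adjusted over the list alone; camera adjusted p = 4.4e-08, adjusted p = 0.53 with an estimated correlation). Immediate early genes rose in 9 of 26, with 1 lower and 16 not passed (9 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.025, adjusted p = 0.897 with an estimated correlation); the prostaglandin synthase Ptgs2 rose by 2.24 ± 0.23.

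Kainate at day 3 left Prss23 higher by 2.85 ± 0.19 (n = 12 against 12), Lox by 2.26 ± 0.27, the matrix protease Mmp9 by 2.02 ± 0.23 and Gfap by 1.91 ± 0.20. Plk5 fell by 2.22 ± 0.28, Gpc3 by 1.78 ± 0.24 and the binding protein Igfbp5 by 1.72 ± 0.21. There were 857 changed genes (502 higher, 355 lower; 158 in laboratory A, 461 in B, but 320 and 201 fitted alone; correlation 0.66 across genes). Microglia markers rose in 14 of 16, with 0 lower and 2 not passed (15 higher and 0 lower adjusted over the list alone), including C1qa at 1.27 ± 0.15 and the lysosomal gene Cd68 at 1.19 ± 0.16. The list was higher by camera (adjusted p = 4.3e-20) and with an estimated correlation (adjusted p = 0.0312). Proliferation genes rose in 9 of 18, with 0 lower and 9 not passed (12 higher and 0 lower adjusted over the list alone; camera adjusted p = 8.5e-08, adjusted p = 0.0725 with an estimated correlation).

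At day 10 after kainate, Prss23 was higher by 2.55 ± 0.19 (n = 12 against 12), Lox by 1.95 ± 0.27, Car10 by 1.82 ± 0.30 and Fosb, an activity-regulated transcription factor, by 1.79 ± 0.45. Gdf10 fell by 1.97 ± 0.20, Plk5 by 1.70 ± 0.28 and the cell adhesion gene Cdh13 by 1.59 ± 0.25. Microglia markers rose in 10 of 16, with 0 lower and 6 not passed (12 higher and 0 lower adjusted over the list alone; camera adjusted p = 8.6e-12, adjusted p = 0.19 with an estimated correlation). Immediate early genes rose in 4 of 26, with 0 lower and 22 not passed (5 higher and 0 lower adjusted over the list alone; camera adjusted p = 1.9e-05, adjusted p = 0.674 with an estimated correlation). Arc was high in few of these rats. It stood at 8.59 and 11.20 in rats 3 and 4 of laboratory A and at 10.00 and 10.45 in rats 2 and 5 of laboratory B, and at 4.93 to 6.94 in the other 8, while Fosb lay beyond the control range in 11 of 12. Of these 4 rats, singled out after their values were seen, 3 (A 3, B 2 and B 5) were nearest to day 1. Of all genes, 676 changed (277 higher, 399 lower; 222 in laboratory A, 96 in B, but 414 and 21 fitted alone; correlation 0.60 across genes).

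SSSE at day 1 raised Trh by 4.34 ± 0.70 (n = 6 against 5), Prss23 by 3.05 ± 0.37, neuropeptide Y (Npy) by 2.85 ± 0.76 and Lox by 2.83 ± 0.58. These lay beyond the control range in 6 of 6 rats, but in 5 of 6 for Npy. Plk5 fell by 3.81 ± 0.56, Gpc3 by 2.86 ± 0.42, Cdh13 fell by 2.66 ± 0.48 and Gdf10 by 2.55 ± 0.38. Granule cell markers fell in 5 of 15, with 0 higher and 10 not passed (0 higher and 6 lower adjusted over the list alone; camera adjusted p = 0.0029, adjusted p = 0.673 with an estimated correlation). Astrocyte markers were higher in 1 of 15 and lower in 7, with 7 not passed (2 higher and 7 lower adjusted over the list alone; camera adjusted p = 0.0335, adjusted p = 0.783 with an estimated correlation). The count was 1348 genes (593 higher, 755 lower), and it rose to 2103 without day 1 rat 6 and fell to 783 without day 1 rat 2, 894 without control rat 2 and 896 without control rat 3.

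By day 3 of SSSE, 338 genes differed (179 higher, 159 lower; n = 5 against 5). Lox rose by 3.04 ± 0.61, Prss23 by 3.01 ± 0.38 and Mmp9 by 2.98 ± 0.22, while Gdf10 fell by 2.24 ± 0.40, Igfbp5 by 2.04 ± 0.28 and Ryr1 by 1.44 ± 0.23. All lay beyond the control range in 5 of 5 rats. Microglia markers rose in 2 of 16, with 0 lower and 14 not passed (9 higher and 0 lower adjusted over the list alone; camera adjusted p = 3.4e-07, adjusted p = 0.522 with an estimated correlation). Day 3 rat 4 had a day 1 score of 0.927, against 0.147 to 0.418 in the other day 3 rats. Without it 215 genes passed, and 214 without the doubted rats and 225 with all 28 groups fitted together; the count was also 219, 196, 189 and 200 without control rats 1, 2, 3 and 4, 180 without day 3 rat 3 and 222 without day 3 rat 5.

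SSSE at day 10 differed from control in 37 genes (19 higher, 18 lower; n = 4 against 5). Ackr3, a scavenging chemokine receptor, rose by 2.25 ± 0.33, Prss23 by 2.17 ± 0.40 and Mmp9 by 1.85 ± 0.24. Fxyd7, a regulator of the sodium pump, fell by 1.56 ± 0.26 and the serotonin receptor Htr5b by 1.19 ± 0.19. All 5 lay beyond the control range in 4 of 4 rats. None of 16 microglia markers passed (0 higher and 0 lower adjusted over the list alone), and their median was 0.39 higher (camera adjusted p = 6.7e-06, adjusted p = 0.538 with an estimated correlation). The count was 23 without control rat 1, 18 without day 10 rat 3, 17 without day 10 rat 6, 17 with a term for the rat number, 20 with all 28 groups fitted together, and 59 without the doubted rats, none of which was a control or a day 10 rat of SSSE.

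Kindling addressed seizures without SE. No gene passed limma's test at stage 2 (523 at an unadjusted p under 0.05) or at stage 4 (504), with 12 rats against 12 controls. The day 1 score at stage 4 averaged 0.148 in laboratory A (0.0285 to 0.246, controls -0.0354 to 0.0809) but -0.0157 in laboratory B. Stage 5 means were 0.178 in A (0.0136 to 0.225) and 0.105 in B (-0.0104 to 0.238), so rats of that stage were mixed. These scores were not tested. At stage 5, Tac3, the precursor of neurokinin B, rose by 2.58 ± 0.51, Car10 by 1.59 ± 0.29, Lox by 1.45 ± 0.25 and Prss23 by 1.45 ± 0.25 (n = 12 against 12). Gdf10 fell by 1.70 ± 0.32, Plk5 by 1.66 ± 0.36, Fst by 1.60 ± 0.26 and Ntf3 by 1.40 ± 0.21. Immediate early genes were higher in 1 of 26 and lower in 4, with 21 not passed (2 higher and 8 lower adjusted over the list alone; camera adjusted p = 0.0793); Fos fell by 1.28 ± 0.27 and Arc by 0.89 ± 0.15. Genes of synaptic vesicles rose in 3 of 23, with 0 lower and 20 not passed (8 higher and 0 lower adjusted over the list alone; camera adjusted p = 2.2e-05, adjusted p = 0.172 with an estimated correlation), such as Syn2 at 0.40 ± 0.08 and Sv2a at 0.37 ± 0.07. Stage 5 changed 764 genes (348 higher, 416 lower), of which 8 were at least 2-fold higher and 12 at least 2-fold lower. Laboratory A passed 105 genes and laboratory B 37, but 5 and 68 fitted alone, with a correlation of 0.51 across genes, and 129 genes passed when all 28 groups were fitted together.

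The 7 genes fixed beforehand moved apart. Npy rose at day 1 by 2.56 ± 0.47 in pilocarpine, 3.21 ± 0.35 in kainate and 2.85 ± 0.76 in SSSE, and at day 10 by 1.40 ± 0.47 in pilocarpine (adjusted p = 0.0486) and 1.38 ± 0.35 in kainate. Npy lay beyond the control range in 4 of 12 rats at pilocarpine day 10, where its mean change was 0.42 in laboratory A and 2.38 in laboratory B, whose rats 1, 2 and 3 stood at 10.37, 12.22 and 11.87 and rats 4, 5 and 6 at 7.70 to 7.93. At kainate day 10 it lay beyond that range in 7 of 12, with 9.66 to 11.52 in rats 3 and 4 of laboratory A and 2 and 5 of laboratory B and 7.36 to 8.93 in the others. The call for Npy at pilocarpine day 10 was lost with a pseudocount of 1, without a filter, with the second array of repeated rats, without the doubted rats and in laboratory A alone. It did not pass at pilocarpine, kainate or SSSE day 3 (1.29, 0.95 and 1.68), at SSSE day 10 (0.50) or at kindling stages 2, 4 and 5 (0.17, 0.27 and 0.35). Gfap rose at all 3 times in pilocarpine and kainate (1.10, 2.43 and 1.36 at days 1, 3 and 10, and 1.96, 1.91 and 1.16), by 1.32 at SSSE day 1 and by 0.62 at kindling stage 5. It was 0.99 and 0.67 without passing at SSSE days 3 and 10 and 0.16 and 0.30 at stages 2 and 4. Calb1, the calcium buffer calbindin, fell at every pilocarpine time (-1.0, -1.28 and -1.0), at kainate days 1 and 10 (-1.04 and -0.78), at SSSE day 1 (-0.80) and at stage 5 (-0.42). It was -0.69 without passing at kainate day 3, -0.64 and -0.16 at SSSE days 3 and 10, and -0.03 and -0.10 at stages 2 and 4. Prox1, which maintains granule cell identity, fell by 0.74 at day 1 in both pilocarpine and kainate. Its other values did not pass: -0.29 and 0.03 at pilocarpine days 3 and 10, -0.26 and -0.24 at the same kainate times, -0.09, -0.14 and 0.04 in SSSE, and -0.04, 0.03 and 0.10 in kindling. Bdnf, a neurotrophin, rose at day 1 by 1.13 in pilocarpine and 0.80 in kainate, at kainate day 10 by 1.21 and at stage 5 by 0.58. At kainate day 10 it stood at 10.56 to 11.50 in the 4 rats with high Arc and at 8.51 to 9.96 in the other 8, against 8.17 to 9.55 in controls. It did not pass at pilocarpine days 3 and 10 (0.72 and 0.84), kainate day 3 (0.62), SSSE days 1, 3 and 10 (0.27, 0.78 and 0.18) or stages 2 and 4 (0.04 and 0.28).

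Fos rose by 2.19 ± 0.59 at pilocarpine day 1, beyond the control range in 6 of 12 rats, and fell at stage 5. Elsewhere Fos did not pass, with 0.87 and 0.63 at pilocarpine days 3 and 10, 0.20, 0.19 and 0.50 in kainate, 0.22, -0.18 and -1.28 in SSSE, and 0.13 and -0.17 at stages 2 and 4. Arc passed at stage 5 alone among the 12 comparisons. Its other values were 0.93, -0.36 and -0.34 at pilocarpine days 1, 3 and 10, -0.25, -0.38 and 0.73 in kainate, 0.11, 0.51 and -0.61 in SSSE, and -0.23 and -0.33 at stages 2 and 4.

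**Figure D2:**
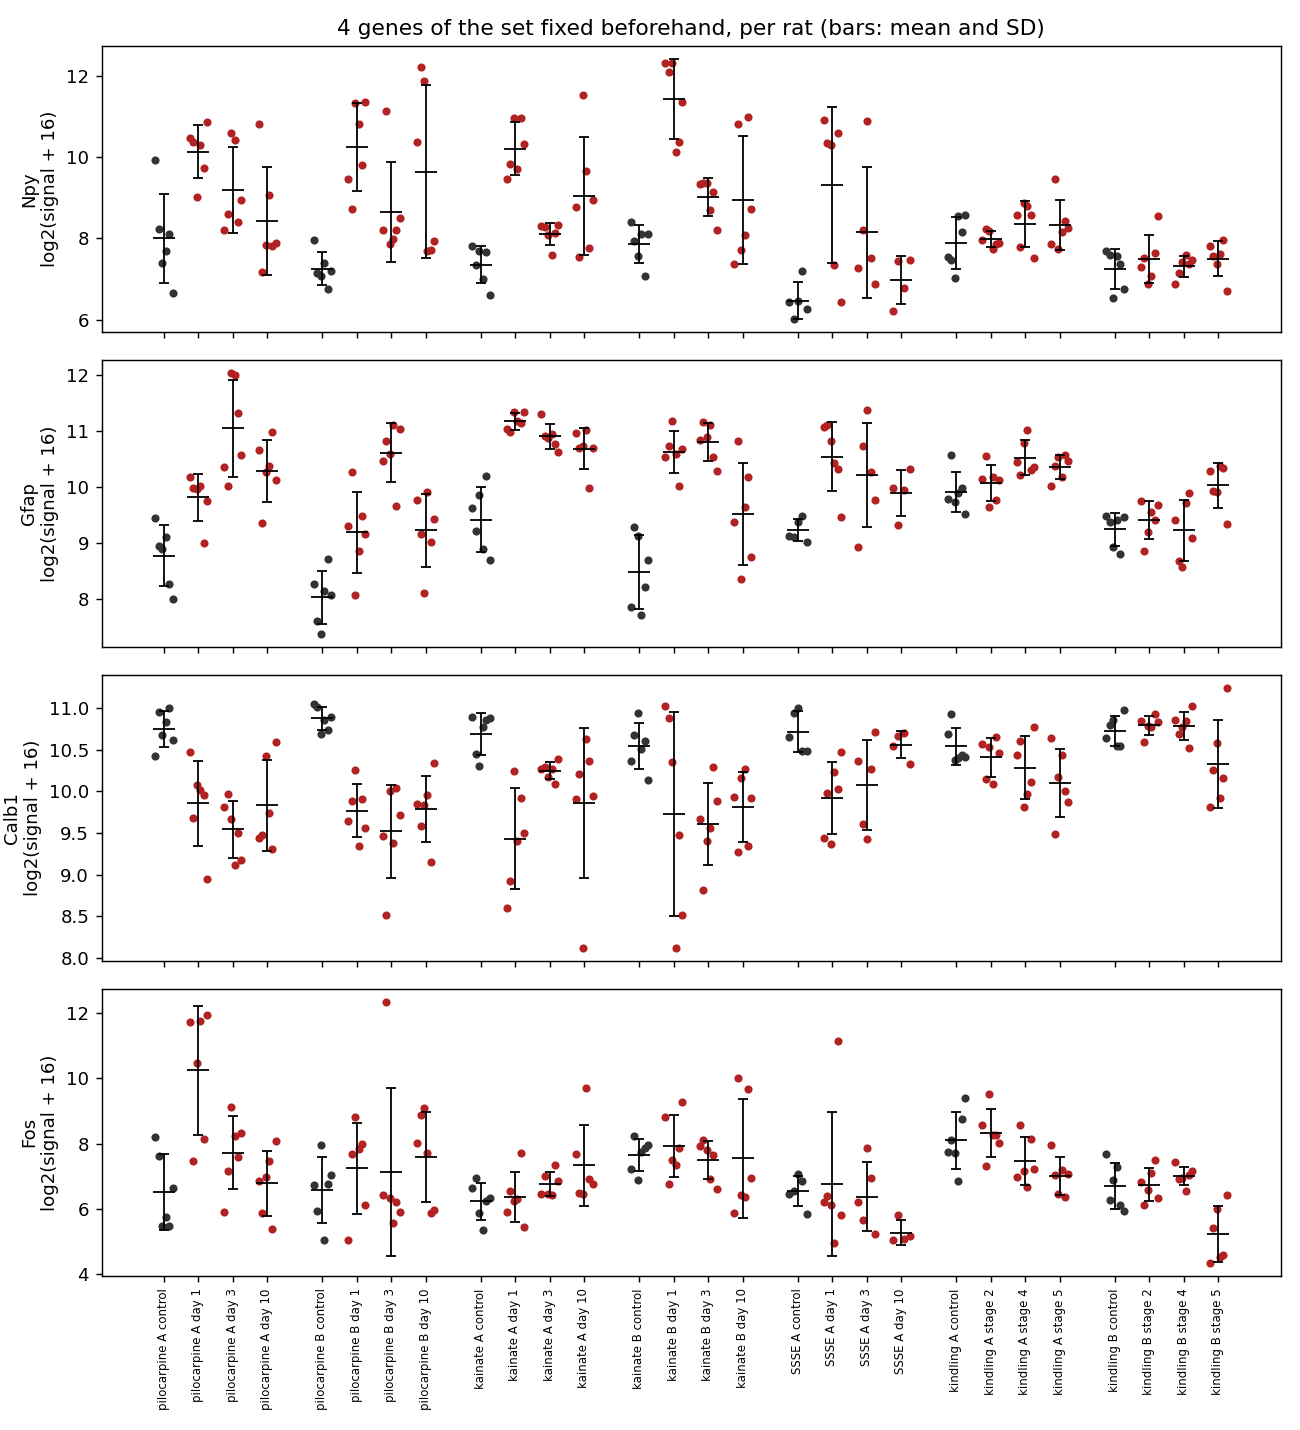
Level of 4 of the 7 fixed genes in each rat, as log2(signal + 16), by model, laboratory (A or B) and time or stage, with controls in dark grey, other rats in red, and bars for the mean and SD. Npy lies above all kainate control rats in 12 of 12 kainate day 1 rats.

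Whether laboratories running the same model gave the same changes was tested directly. In pilocarpine 29 genes differed between A and B, by an F-test over the 3 times. First among them were Calca, the precursor of calcitonin gene-related peptide (A minus B 2.60, 1.26 and -1.74 on the log2 scale at days 1, 3 and 10; adjusted p = 0.0298), Psmd6 and the complement gene C3 (0.19, -0.09 and 1.59). The pilocarpine count was 0 to 210 under other settings, including 1 after quantile normalization, 0 without the doubted rats and 210 with the first array alone of the 5 laboratory A controls hybridised again; no treated pilocarpine rat was. In kainate 1 gene differed, Col11a1, a fibrillar collagen (-2.09, -0.74 and -0.52; adjusted p = 0.0229), with 520 at an unadjusted p under 0.05; the count was 0 with a pseudocount of 1. In kindling limma called 0 (532 at an unadjusted p under 0.05).

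Comparing the times of a model, 2642 genes differed in pilocarpine. Rasd1, a small G protein, stood at 1.06, -1.07 and -0.87 at days 1, 3 and 10, and Dpy19l3 at -1.39, -0.19 and 0.07 (adjusted p = 5.2e-10). In kainate 3793 differed, with Rreb1 at -2.98, -1.0 and -0.61 (adjusted p = 1.3e-17) and Hspb1 at 4.32, 1.58 and 0.19. In SSSE 343 differed, with Cpne9 at -0.99, 0.26 and 0.22 and the microglial receptor P2ry12 at -0.76, 0.79 and 0.72 (adjusted p = 0.00471). The SSSE count fell to 13 without day 1 rat 3, whose labels conflict, and to 57 with a term for the rat number, and rose to 664 without the doubted day 3 rat. In kindling 107 differed, with Calhm2 at -0.01, -0.20 and -0.55 and Ddit4l, an inhibitor of mTOR signalling, at -0.06, -0.31 and -1.42 at stages 2, 4 and 5, and 193 differed without the kindled rat with conflicting labels.

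The SE models were then compared for shared changes. At day 1, 735 genes changed the same way in all 3 (311 higher, 424 lower), where independent lists would share 20.9 higher and 23.8 lower, and 21 genes passed in opposite directions between models. Trh (mean of the 3 models 4.51), Lox (4.19), Prss23 (3.55) and Npy (2.87) were among the largest rises, and Plk5 (-3.67), Gpc3 (-2.78), Gdf10 (-2.44) and Rreb1 (-2.44) among the largest falls. At day 3, 136 genes were shared (85 higher, 51 lower; 0.646 and 0.206 by independent lists), among them Lox (2.67), Prss23 (2.61), Mmp9 (2.05), Gdf10 (-1.97) and Ryr1 (-1.73). At day 10, 20 were shared (11 higher, 9 lower; 0.0187 and 0.0341 by independent lists), including Prss23 (2.09), Palmd (1.70), Mmp9 (1.45), Igfbp5 (-1.40), Fxyd7 (-1.30) and Ryr1 (-1.26), and 13 were shared with a pseudocount of 1 and 11 with a term for the rat number. Effects correlated across genes at 0.84 between pilocarpine and kainate, 0.72 between pilocarpine and SSSE and 0.79 between kainate and SSSE at day 1. In the same order these were 0.70, 0.59 and 0.72 at day 3 and 0.57, 0.46 and 0.47 at day 10.

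Tests of a difference between SE models called 615 genes at day 1, 48 at day 3 and 7 at day 10. At day 1 Xbp1, a regulator of the unfolded protein response, stood at 0.74 in pilocarpine, -0.15 in kainate and -0.08 in SSSE (adjusted p = 3.7e-07), and doublecortin (Dcx), a marker of young neurons, at -0.39, 0.73 and 0.98. At day 3 the cell cycle genes Cdca3 (1.45, 0.71 and 0.35; adjusted p = 0.000884) and Cdk1 (1.62, 0.93 and 0.37) and the complement gene C1qc (1.91, 1.18 and 0.44) differed. At day 10 the first were Ube2m and Acp2. Models came from different laboratories, so model and laboratory cannot be told apart, and other assignments of the 5 laboratories to models gave up to 859, 206 and 561 genes at days 1, 3 and 10. The first principal component also set pilocarpine rats (scores 1.34 to 51.9) apart from SSSE rats (-37.8 to -5.37). Kainate laboratory A lay mostly on the side of SSSE and laboratory B on that of pilocarpine. Pilocarpine and SSSE cannot be told apart from this split of the arrays, whose cause was not tested. Other settings gave 24 to 154 genes at day 3 and 1 to 133 at day 10.

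Kindling stage 5 resembled the SE models in direction. Of its 764 genes, 78.7% (kainate day 1) to 88.0% (kainate day 3) had the same sign as in an SE comparison, and effects correlated across genes at 0.36 (pilocarpine day 1) to 0.53 (kainate day 10). With kainate day 3, 114 genes were higher and 116 lower in both, where independent lists would share 16.2 and 13.7, and 3 passed in opposite directions. With kainate day 1 these were 188 and 243 (77.4 and 80.6 by independent lists) with 57 opposite, and with pilocarpine day 1, 143 and 229 (55.1 and 67.7) with 36 opposite. Lox, Prss23, Car10 and Serinc2 were among the largest rises at stage 5 and Gdf10, Plk5, Ddit4l and Igfbp5 among the largest falls.

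**Figure D3:**
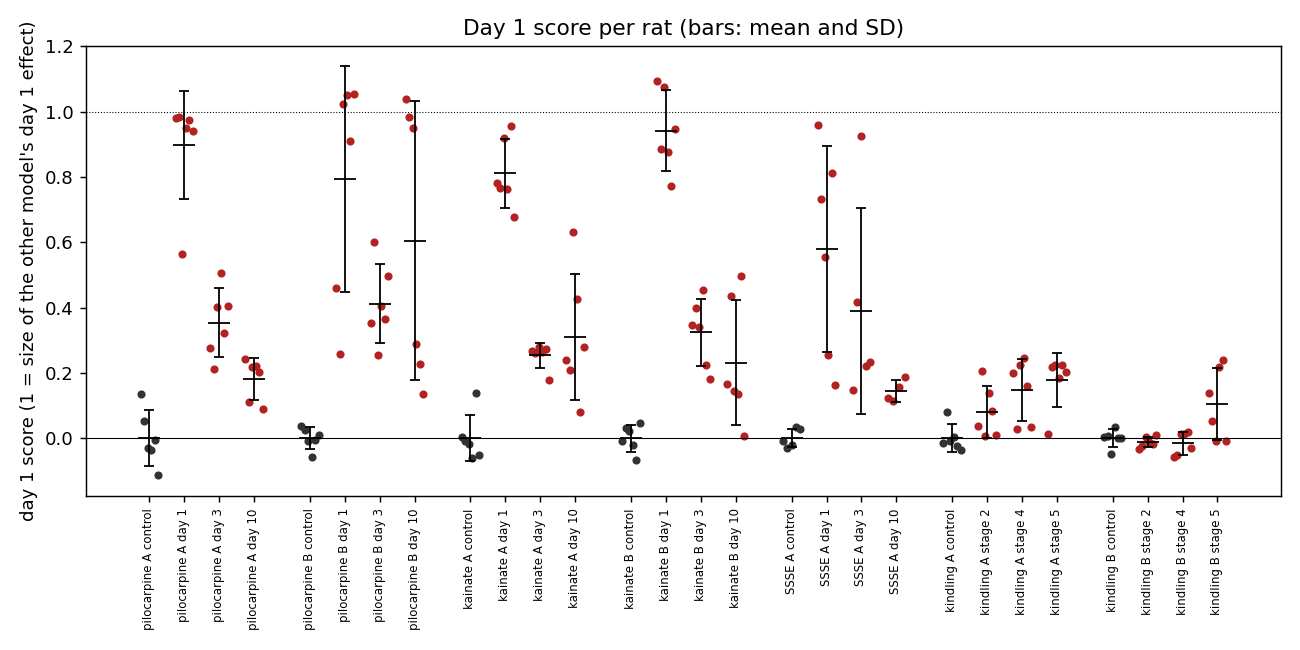
Day 1 score of each rat, the size of its change along the day 1 effects of another model (1 is full size), by model, laboratory and time or stage, with controls in dark grey, other rats in red, and bars for the mean and SD. Pilocarpine laboratory B day 10 rats 1, 2 and 3 lie at 1.04, 0.98 and 0.95, and SSSE day 3 rat 4 at 0.927.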

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

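The 6 tests that weigh explanations below were chosen only after the result was seen, while the splits of the rats were planned.

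The first pattern was the 3 pilocarpine laboratory B day 10 rats (1, 2 and 3) with day 1 scores of 1.04, 0.98 and 0.95, while day 10 rats 4, 5 and 6 of that laboratory had 0.29, 0.23 and 0.14. To weigh lower RNA quality of these rats, other pilocarpine rats outside day 1 with an actin ratio at least as high were taken. These 5 had a median score of 0.111 (-0.0372 to 0.404). As 2 of them were controls, whose scores are centred on 0, the 3 treated ones count: their median was 0.204 (0.111 to 0.404), below the lowest of the pattern, though they are few. All 3 came from laboratory A, and day 10 rats 2 and 5 among them were doubted rats. Within laboratory B at day 10 the actin ratio was 4.55, 4.55 and 4.66 in rats 1, 2 and 3. In rats 4, 5 and 6 it was 4.13, 4.11 and 4.09. A high actin ratio thus came without a high score in laboratory A, but lower RNA quality stays open in laboratory B. An explanation by day 1 and day 10 rats of this laboratory exchanged stays open: 2 of its 6 day 1 rats were nearest to a later time (rats 1 and 2, scores 0.459 and 0.259), fewer than the 3 it needs. A single wrong label, an exchange with outside samples and a later seizure in these rats also stay open, as none was tested.

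The second pattern was SSSE day 3 rat 4, with a score of 0.927 and nearest to day 1. As it was picked by that score, its nearness to day 1 adds little. An exchange of day 1 and day 3 rats of SSSE met its prediction, since 2 SSSE day 1 rats (4 and 6, scores 0.256 and 0.162) were nearest to a later time. Rat 6 was nearest to day 3, but rat 4 to day 10 (correlations 0.462, 0.470 and 0.498 at days 1, 3 and 10). That test could have found none, but any such day 1 rat would have met it, so an exchange merely stays open. A milder SE in those day 1 rats and later seizures in the day 3 rat were not tested and stay open. The nearest-time assignment told day 3 from day 10 poorly: 0 of 4 SSSE day 10 rats and 1 of 6 pilocarpine laboratory A day 10 rats were nearest to their own time.

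The third pattern was the rise of the microglia markers at day 3. If fewer granule cells were captured and all other cell types entered evenly, markers of every other cell type would rise alike. The other lists lay below the microglia median by different amounts. The furthest, chosen for that reason, was that of the oligodendrocyte markers, whose median lay apart from the microglia median by -1.01 (SE 0.293) in pilocarpine and -0.886 (SE 0.147) in kainate. The astrocyte, endothelial and interneuron differences were -0.657 (SE 0.335), -0.720 (SE 0.293) and -0.911 (SE 0.343) in pilocarpine, the first of them within 2 SE, and -0.599, -0.673 and -0.803 in kainate. These standard errors come from resampling the genes of each list and not the rats. They treat the genes of a list as independent and do not measure the spread between rats. The unequal medians argue against such an even entry as the whole account. Astrocyte and endothelial medians of 0.48 and 0.42 in pilocarpine leave a part of it open. Cells near the layer need not enter evenly, so the test cannot decide whether the captures held fewer granule cells. Of the 16 microglia markers, 0 are in another list and 2 lay above the array median in most control rats. Lyz2 went from a signal of 161 in controls to 1260 at pilocarpine day 3, and C1qa from 57.7 to 160.0 at kainate day 3. More microglia within the captured layer, or higher expression in each, stay open and were not tested.

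Single rats far from the rest of their group were sought in 280 combinations of group and measure, where chance gives about 14, and 22 were found. Pilocarpine laboratory B day 3 rat 2 stood out in Fos (12.32), Arc (9.89) and Npy (11.14), all as log2 levels, and in the Gapdh 3' to 5' ratio (2.58). SSSE day 1 rat 5 stood out in Fos (11.15) and Arc (11.44), and SSSE day 3 rat 4 in Arc (10.30). SSSE control rat 4 stood out in Bdnf (8.91) and SSSE day 10 rat 2 in Fos (5.83). In kainate laboratory A, day 3 rat 4 stood out in Npy (7.59), day 3 rat 3 in Prox1 (10.45), day 10 rat 5 in Gfap (9.99) and day 10 rat 3 in Calb1 (8.12). Pilocarpine laboratory A day 1 rat 5 stood out in Gfap (9.0), and day 1 rat 3 of the same group in its day 1 score (0.564). Other day 1 scores apart from their group were those of kindling laboratory A control rat 2 (0.0809) and stage 5 rat 1 (0.0136), and of kainate laboratory A control rat 5 (0.137) and day 3 rat 6 (0.178). Kindling laboratory A stage 5 rat 2 stood out in the actin (3.31) and Gapdh (1.48) ratios, and pilocarpine laboratory B control rat 1 in the actin ratio (5.15).

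Effects that differed between groups by a test of the difference itself were those between laboratories (29 genes in pilocarpine, 1 in kainate) and between times (2642 in pilocarpine, 3793 in kainate, 343 in SSSE and 107 in kindling). Between SE models they numbered 615, 48 and 7 at days 1, 3 and 10, by a test that called more unchanged genes in simulated data than its threshold implies.

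Other splits of the same rats bear on these counts. For 10 of the 12 comparisons with control, 1 of 100 splits, the real one, gave as many genes, so chance can be excluded. Real count and highest other were 3454 and 367, 1255 and 223, and 961 and 625 at pilocarpine days 1, 3 and 10, then 4478 and 2148, 857 and 58, and 676 and 12 in kainate. They were 1348 and 860, 338 and 6, and 37 and 10 in SSSE, and 764 and 37 at kindling stage 5. A count of 0 cannot be tested in this way, as all 100 splits must give as many, which concerned kindling stages 2 and 4 (highest other 2 and 1) and the difference between kindling laboratories (highest other 2). Among tests between times, 1 of 100 splits gave as many in pilocarpine (2642, highest other 35) and kainate (3793, highest other 54), so chance can be excluded there. In kindling 2 gave as many (107, highest other 150) and in SSSE 4 (343, highest other 1484), fewer than the planned 5 in 100. Other splits of both models exceeded the real count, and with many counts tried such shares can arise by chance, so chance is not excluded for them. The SSSE count also fell far without its rat with conflicting labels, and with a term for the rat number. A split of SSSE that called several times the real count points to a structure of those samples, whose nature was not tested. Between laboratories, 1 of 100 splits gave as many genes in pilocarpine under the main settings (29 genes, highest other 15). That is the lowest share the splits can give, but with many counts tried a single such share can arise by chance. Chance is therefore not excluded for pilocarpine, nor for kainate (13 of 100, with 1 gene and highest other 21). The splits were tried under the main settings alone. The pilocarpine count all but vanished under some other settings, so the splits cannot tell whether it depends on the processing. Assignments of the 5 SE laboratories to models number 15, too few to exclude chance. Of these 4, 6 and 12 gave as many genes at days 1, 3 and 10, with real counts of 615, 48 and 7 and highest others of 859, 206 and 561. For genes shared by SE models, 1 of 100 splits gave as many at each time (735, 136 and 20, highest other 0). Splits that call few genes in each model can hardly share any, so this tests that each model has changes and not that they are shared.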

How the results depend on the processing

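The second array of repeated rats and leaving out the 5 doubted rats were tests chosen only after the result was seen. The cause of each move was not tested unless stated. Counts kept within 1.5 times their value in 22 of 25 results with a pseudocount of 1, 22 after quantile normalization, 24 without a filter, 23 with a stricter one, and 23 with the mean of all probe sets. This held for 22 with the first array, 24 with the second, 23 without rats with contradicting labels, 21 with a term for the rat number and 18 without doubted rats. Among 567 calls on named genes in the comparisons, 542 kept their side of the threshold after quantile normalization (22 lost, 3 gained) and 551 with a pseudocount of 1 (16 lost). With all 28 groups fitted together 62 were lost and 4 gained, with laboratory A alone 170 were lost and 271 kept, and with laboratory B alone 162 were lost and 280 kept. Exactly 1 reversed: Scn3a at pilocarpine day 10 was -0.0359 in laboratory A alone. The largest rises and falls were chosen with the same sign in every laboratory, so they could not reverse in a laboratory alone. A changed sign in a gene that passed under neither setting was not counted. The lack of reversals therefore says little about agreement between laboratories. Dim genes near the array background limit what can be called.

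With a pseudocount of 1, the laboratory difference was 0 genes in pilocarpine and 0 in kainate, and 13 genes were shared at day 10. Quantile normalization gave 1 for the pilocarpine laboratory difference, and 87 and 23 genes between SE models at days 3 and 10. At day 10 that difference was 16 without a filter, 11 with a stricter filter (24 at day 3) and 2 with the mean of all probe sets, which gave 17 between pilocarpine laboratories. The first array of repeated rats gave 210 between pilocarpine laboratories and 154 and 133 between SE models at days 3 and 10, and the second gave 1 at day 10. Controls 1 to 5 of pilocarpine laboratory A were the only pilocarpine rats hybridised again, so the difference between its laboratories moved with these controls and with no other rat of the model. Between SE models a kainate day 3 and an SSSE day 1 rat changed array as well, and the parts were not separated. Without the rats with contradicting labels, 13 genes differed between times in SSSE and 193 in kindling. A term for the rat number gave 17 genes at SSSE day 10, 57 between SSSE times, 29 between SE models at day 10 and 11 shared at day 10. Leaving out the doubted rats gave 580 at pilocarpine day 10, 214 at SSSE day 3, 59 at SSSE day 10, 0 between pilocarpine laboratories, 664 between SSSE times, and 104 and 3 between SE models at days 3 and 10. Fitting all 28 groups together, which pools the spread of all models, gave 2553 and 2505 at pilocarpine days 3 and 10, 225 and 20 at SSSE days 3 and 10 and 129 at kindling stage 5. Fewer rats entered with laboratory A alone, which gave 461 and 67 at pilocarpine days 3 and 10, 320 and 414 at kainate days 3 and 10 and 5 at stage 5. Laboratory B alone gave 1440 and 379 at pilocarpine days 1 and 3, 2686, 201 and 21 at kainate days 1, 3 and 10 and 68 at stage 5. Lists called fell from 78 to 4 with an estimated correlation.

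Leaving out each rat in turn gave 3145 to 3690, 992 to 1348 and 668 to 1275 genes at pilocarpine days 1, 3 and 10, 4220 to 4484, 707 to 865 and 504 to 875 in kainate. It gave 783 to 2103, 180 to 480 and 17 to 42 in SSSE, 0 to 0 at kindling stages 2 and 4 and 531 to 1089 at stage 5. For SSSE day 1 the count was 2103 without day 1 rat 6, 783 without day 1 rat 2, 894 without control rat 2 and 896 without control rat 3. For day 3 it was 219, 196, 189 and 200 without control rats 1, 2, 3 and 4, and 180, 215 and 222 without day 3 rats 3, 4 and 5. For day 10 it was 23 without control rat 1, 18 without day 10 rat 3 and 17 without day 10 rat 6.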

Other observations

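Potassium channel genes moved both ways at kainate day 1, and no test in this part was chosen only after the result was seen. Of 35 potassium channel genes at kainate day 1, 9 rose, 10 fell and 16 did not pass (9 higher and 10 lower adjusted over the list alone; camera adjusted p = 0.741); the list's median was 0.06 and its mean -0.05. Kcnip2, a partner of A-type channels, fell by 1.88 ± 0.13 in kainate, 1.38 ± 0.24 in pilocarpine and 1.10 ± 0.23 in SSSE at day 1, while Kcnip3 rose by 1.43 ± 0.17 in kainate. Sodium and calcium channel genes rose in 3 of 22 and fell in 7, with 12 not passed (3 higher and 7 lower adjusted over the list alone; camera adjusted p = 0.11), among them Scn4b, by 1.17 ± 0.17. Genes of GABA signalling fell in 5 of 13, with 0 higher and 8 not passed (0 higher and 5 lower adjusted over the list alone; camera adjusted p = 0.0335, adjusted p = 0.53 with an estimated correlation). The receptor subunits Gabra5 and Gabrd fell by 1.68 ± 0.13 and 1.53 ± 0.16 and the chloride extruder Slc12a5 by 0.91 ± 0.10. Glutamate receptor genes fell in 12 of 23, with 3 higher and 8 not passed (3 higher and 13 lower adjusted over the list alone; camera adjusted p = 0.0394, adjusted p = 0.632 with an estimated correlation) and Grm3 fell by 1.52 ± 0.13.

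Young neuron genes rose in 8 of 20 at kainate day 1, with 2 lower and 10 not passed (8 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.182), with Tubb6 at 1.93 ± 0.16 and Sox11 at 1.70 ± 0.18. Heat shock and stress genes at pilocarpine day 1 rose in 13 of 29, with 0 lower and 16 not passed (14 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.000625, adjusted p = 0.53 with an estimated correlation), with the crystallin Cryab at 2.02 ± 0.35. Neuropeptide and growth factor genes rose in 9 of 20, with 1 lower and 10 not passed (10 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.00285, adjusted p = 0.254 with an estimated correlation). Oligodendrocyte markers fell in 3 of 14 at pilocarpine day 1, with 0 higher and 11 not passed (0 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.043, adjusted p = 0.897 with an estimated correlation). At the same time 2 of 10 endothelial markers rose and 1 fell, with 7 not passed (2 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.741). Of 12 interneuron markers, 1 rose and 1 fell, with 10 not passed (1 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.969; median -0.03, mean 0.15), and 5 of the 12 are in other lists. Of 13 markers of neighbouring pyramidal and mossy cells, 4 rose and 2 fell, with 7 not passed (4 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.577; median -0.13, mean 0.34), with the imprinted gene Nnat at 2.42 ± 0.43. None of 7 choroid plexus and blood genes passed (0 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.959; median 0.01, mean -0.06). Of 57 genes of oxidative phosphorylation, 4 rose and 2 fell, with 51 not passed (0 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.857), and of 34 ribosomal and translation genes 4 rose and 0 fell, with 30 not passed (1 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.346). At kindling stage 4, where no gene passed, 0 of 57 genes of oxidative phosphorylation passed (0 higher and 0 lower adjusted over the list alone), and their median was 0.06 (camera adjusted p = 1.4e-05, adjusted p = 0.696 with an estimated correlation).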
